A study of Oryza sativa with 12 samples.

How the data were processed

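RNA from 1 mm root tips of rice seedlings at day 3 was measured on a two-colour Agilent rice array. Per the labels, 4 groups (wild type and rss3, each with 0 or 100 mM NaCl) had 3 biological replicates each, and 400 ng of RNA was labelled. Each array carried a sample in Cy5 and a wild-type 0 mM reference in Cy3, with no dye swap. Each array held 45151 spots, of which 1537 control spots were left out, and the other 43614 carried 42465 distinct probes. Of these, 41908 named a rice locus (29690 loci) and 557 did not.

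Agilent Feature Extraction 10.5.1.1 read the arrays, per the file headers. The deposited mean spot signals and median local backgrounds are intensity values with no normalization. The deposited processed signals are also intensity values, background-subtracted with spatial detrending and dye-normalized by linear and LOWESS steps. The deposited log ratio is the log10 of processed Cy5 over processed Cy3. The deposited flags and spot numbers are other values, the latter used to join the authors' table. In that table the authors gave the p-value (p_value) of a 2-way ANOVA (genotype, stress and interaction) and of one-sided RankProduct tests for each spot. The authors also gave the RankProduct pfp, a score that estimates the share of false positives and can exceed 1. The input values and software version of that table are not stated.

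The mean signals were background-corrected here by normexp with an offset of 50 and normalized within each array by loess, giving log2 ratios of Cy5 over Cy3 (limma 3.58.1, R 4.3.3, version 1.17.8 of data.table, statmod 1.5.0). Adding the offset to both channels shrinks the log ratios of dim spots, so their changes may be understated. Spots flagged by Agilent as outliers (37 to 67 per array) were left out, and spots of the same probe were averaged. A probe was tested if it was well above background in Cy5 on all 3 arrays of at least 1 group (31352 probes, 21680 loci). No spot was saturated, and 27568 probes were well above background on all arrays. Within groups, log ratios correlated between arrays at 0.88 to 0.94, except wild type 0 mM (0.41 to 0.54), where sample and reference were the same kind of RNA and little signal is left.

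A linear model with group as its only term was fitted to all 12 arrays with empirical Bayes variances. The comparisons were the salt effect in each genotype, the rss3 effect without and with salt, and their interaction. P-values were adjusted by Benjamini-Hochberg over the probes tested, with a threshold of 0.05. Replicate number is also the slide. Of 18 pairs of arrays with the same number, 6 had deviations from their group means correlated above 0.1 (range -0.30 to 0.36), and 2 of 12 arrays correlated best with their own number, so the numbers were not used as pairs and a block was only an alternative.

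Gene lists were made from words in the product names on the array. They covered jasmonate synthesis and signalling, jasmonate response and defence proteins, class III peroxidases, expansins and xyloglucan enzymes, cellulose and matrix polysaccharide synthesis, pectin enzymes with extensins and arabinogalactan proteins, and lignin with phenylpropanoid genes. Others were late embryogenesis and abscisic acid response, sodium and potassium transport, aquaporins, oxidative stress, heat shock, mitosis, DNA replication, core histones, ribosomal proteins, translation factors, auxin, cytokinin and ethylene, AP2/ERF, WRKY and NAC, terpenoids, nutrient and metal transport, Casparian strip and root hair, secondary wall and vascular, photosynthesis, and seed storage. Each locus was represented by its brightest kept probe. Lists with at least 5 measured loci were tested by camera with its preset correlation of 0.01, adjusted over 26 lists in each comparison, beside camera with an estimated correlation and fry. Camera with the preset called 12, 14, 5, 7 and 8 lists in the 5 comparisons and fry 19, 23, 18, 20 and 5. With an estimated correlation camera called 0 in each. Counts of members are over all genes unless said to be adjusted over the list alone. Lists overlapped, most between defence proteins and AP2/ERF factors (31 measured loci).

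The genes named in each comparison followed a rule. It named RSS3, then the 6 largest rises and 6 largest falls past the threshold with a named product whose 3 arrays did not overlap those of the other group (chance gives 10%; no such condition for the interaction), 1 probe per locus. It also named up to 3 members with the largest change past the threshold, or the brightest member if none passed, from 5 fixed lists (jasmonate, defence and 3 cell wall lists) and the 5 other lists with the smallest camera p. The text prints part of these. The groups, comparisons, named-gene rule and alternatives were chosen before the data were examined, except lists without members matched by accident, and a separate look at the results without rss3 100 mM replicate 3.

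The method was tested on simulated data with the spread of these arrays, 200 changed probes among 31305 and 5 runs. Changes of 0.5 on the log2 scale were recovered in 69.9% to 74.9% of cases for comparisons of 2 groups and 36.1% for the interaction. A list of 32 loci shifted by 0.3 was called in 20 of 20 runs by both versions of camera, where simulated genes were independent. Alternatives were Agilent's processed signals, median centring, Cy5 alone with quantile scaling, no background subtraction, other probe filters, the mean of all probes of a locus, other variance models, replicate or slide blocks, only the arrays of the groups compared, leaving out each array, and the authors' table. No genome was at hand, so no positions are given. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.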

Results

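Gene expression was measured on 12 rice arrays in 1 mm root tips of seedlings at day 3. The seedlings were wild type (cultivar Nipponbare) or the rss3 mutant (rice salt sensitive 3), grown on medium with 0 or 100 mM NaCl. Each of the 4 groups had 3 biological replicates, and each array set 1 sample (Cy5) against a wild-type 0 mM reference (Cy3). Values are log2 ratios of sample over reference, and changes are differences between group means with the standard error of the limma fit (n = 3 arrays per group). Between 68.2% and 77.0% of the probes were well above background in Cy5, and between 61.8% and 64.7% in Cy3. The array of rss3 with salt, replicate 3, was the brightest in Cy5, with a median signal of 368 against 177 to 312 on the other arrays. After filtering, 31352 probes for 21680 loci were tested. The number of arrays limits the precision, and in simulated data of this size 96.1% to 98.5% of changes of 1 on the log2 scale were recovered in the comparisons of 2 groups, and 91.3% in the interaction.

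**Figure D1:**
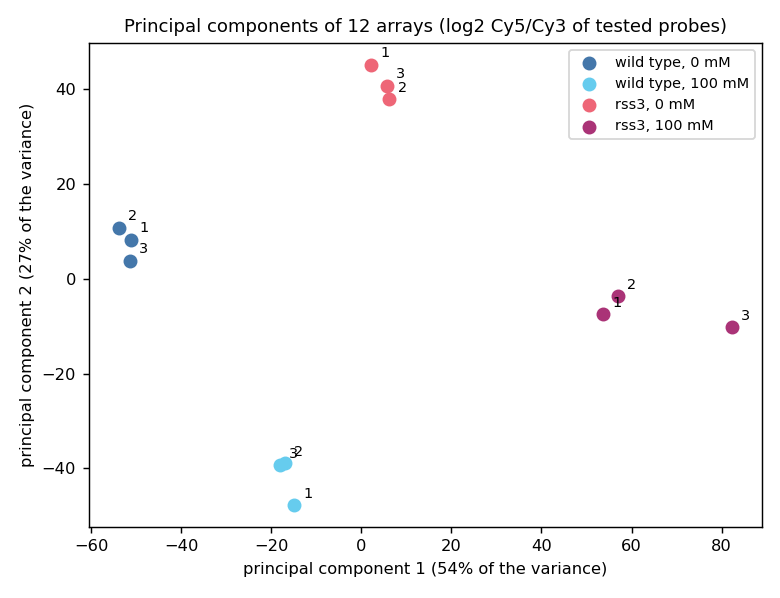
Each point is 1 of the 12 arrays, placed by the first principal component (horizontal axis, 54% of the variance) and the second (vertical axis, 27%), coloured by group and numbered by replicate. The 4 groups sit apart from each other, and rss3 with salt replicate 3 lies at 82.3 on the first component, against 53.7 and 56.9 for the other replicates of its group.

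The mutated gene was followed by the probe of Os11g0446000, taken to be RSS3. The array names this locus only a conserved hypothetical protein and the files do not link it to RSS3. Where the probe lies relative to the mutation is also not known, so its values do not check the genotype labels. Its mean log2 ratio was 0.13 ± 0.10 (SD, n = 3) in wild type without salt, 0.06 ± 0.16 with salt, -0.22 ± 0.09 in rss3 without salt and 0.09 ± 0.12 in rss3 with salt. The transcript was lower in rss3 without salt, by -0.35 ± 0.09 (adjusted p = 0.013, same sign on 3 of 3 slides), and rose with salt in rss3, by 0.30 ± 0.09 (adjusted p = 0.024, 3 of 3 slides). Its salt effect in wild type (-0.07, adjusted p = 0.60), its rss3 effect with salt (0.03, adjusted p = 0.86) and its interaction (0.37 ± 0.13, adjusted p = 0.082) did not pass the test. The call without salt was lost without rss3 0 mM replicate 1 (-0.30) or wild type 0 mM replicate 3 (-0.29). The call for salt in rss3 was lost without rss3 0 mM replicate 1 (0.26) or 2 (0.29), or rss3 100 mM replicate 1 (0.29) or 3 (0.25), and without wild type 100 mM replicate 1 the interaction passed (0.46). Median centring in place of loess also ended both calls (-0.22 and 0.33), and Agilent's processed signals ended the call for salt in rss3 (0.26).

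The first comparison asked what salt does to gene expression in the wild-type root tip. By camera with its preset correlation, lists of peroxidases, expansins and aquaporins rose with salt, and those of histones, ribosomal proteins and DNA replication fell, each with only part of its members past the threshold. With an estimated correlation 0 of 26 lists were called (smallest adjusted p = 0.27). The largest rises among genes with a product name were a pepsin-family peptidase (Os02g0720900, 3.44 ± 0.17), mannose-binding lectins (Os03g0245500, 3.34 ± 0.50, and Os10g0155100, 3.01 ± 0.37), a ubiquitin (Os09g0483400, 3.10 ± 0.18) and peroxidase P7 (Os06g0547400, 2.99 ± 0.20). The deepest falls were a germin-family protein (Os08g0231400, -4.44 ± 0.18), pepsin-family peptidases (Os10g0537800, -4.32 ± 0.38, and Os10g0538200, -3.56 ± 0.31), a transferase (Os10g0122500, -3.74 ± 0.13), a xyloglucan fucosyltransferase (Os04g0449200, -3.69 ± 0.14) and the pathogenesis-related protein PR1a (Os07g0129200, -3.31 ± 0.32). Values are those of the brightest probe, and the 5 tested probes of Os02g0720900 ranged from 1.36 to 3.44. In all, 5895 probes were higher and 4753 lower with salt (10648 of 31352), of which 754 and 241 changed at least 2-fold.

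Among the genes of growth and division, 149 of 269 measured ribosomal protein loci fell and 1 rose (163 and 3 adjusted over the list alone, median -0.18), including the L36 protein Os01g0840700 (-0.50 ± 0.06) and the S11 family protein Os05g0292500 (-0.55 ± 0.07). Camera called this list with an adjusted p of 4.1e-17, which was 0.27 with an estimated correlation. Of 46 core histone loci 37 fell and 1 rose (median -0.42, adjusted p = 3.9e-16, or 0.27 with an estimated correlation), among them the H4 genes Os05g0466600 (-0.70 ± 0.09) and Os02g0684500 (-0.63 ± 0.06) and the H3 gene Os06g0160100 (-0.63 ± 0.07). Ribosome assembly and translation factors fell in 29 of 72 loci and rose in 2 (median -0.14, adjusted p = 1.0e-05, or 0.27 with an estimated correlation), and DNA replication genes in 21 of 49 with 2 rises (median -0.17, adjusted p = 0.00014, or 0.27 with an estimated correlation). Examples are the elongation factor P homologues Os12g0115900 and Os11g0116400 (each -0.45 ± 0.06), a clamp loader subunit (Os03g0792600, -0.48 ± 0.05) and DNA polymerase alpha subunit B (Os12g0242900, -0.46 ± 0.06). Cyclin, kinesin and mitosis genes fell in 35 of 96 loci and rose in 14 (median -0.10, adjusted p = 0.023, or 0.57 with an estimated correlation). That call was lost without wild type 100 mM replicate 2 (median -0.12), wild type 100 mM replicate 3 (-0.09) or wild type 0 mM replicate 3 (-0.08), and with median centring, where the median was 0.01 but -0.10 relative to the median of all probes. Median centring also ended the calls of the named ribosomal, elongation factor P, clamp loader and polymerase genes (-0.28 to -0.39).

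Among the genes of the cell wall and of transport, 48 of 96 class III peroxidases rose and 12 fell (median 0.39, adjusted p = 2.3e-06, or 0.27 with an estimated correlation). These enzymes use hydrogen peroxide in the cell wall. Peroxidase 27 (Os07g0531400) rose by 2.04 ± 0.12, and Os03g0339400, not above background without salt, by 1.95 ± 0.17. Where a group was at background, the size of a change is uncertain. Expansins, which loosen walls, and xyloglucan enzymes rose in 40 of 78 loci and fell in 13 (median 0.36, adjusted p = 1.0e-05, or 0.27 with an estimated correlation), led by EXPA19 (Os03g0428700, 2.60 ± 0.24) and EXPA18 (Os03g0155900, 2.52 ± 0.19). Of 11 aquaporins 7 rose and 0 fell (median 0.47, adjusted p = 0.00015, or 0.28 with an estimated correlation). Lignin and phenylpropanoid genes rose in 20 of 49 loci and fell in 4 (median 0.21, adjusted p = 0.0024, or 0.48 with an estimated correlation), with the caffeic acid methyltransferase Os08g0157500 at 2.72 ± 0.22. Pectin enzymes, extensins and arabinogalactan proteins rose in 42 of 98 loci and fell in 13 (median 0.14, adjusted p = 0.0096, or 0.35 with an estimated correlation), including a pectinesterase (Os07g0675100, 1.76 ± 0.07) and an extensin-like protein (Os01g0594300, 1.59 ± 0.13). Sodium and potassium transport genes rose in 15 of 44 loci and fell in 3 (median 0.10, adjusted p = 0.047, or 0.27 with an estimated correlation), a call lost without wild type 100 mM replicate 1 (0.07) or 3 (0.05) or wild type 0 mM replicate 2 (0.09). It also ended with processed signals (0.10) and with no filter on dim probes (0.04). When members matched by accident were taken out of the lists, this list kept all 44 loci (0.10). Its camera adjusted p then became 0.051 through the adjustment over the lists, whose other members had changed. Median centring ended the calls for lignin (0.25) and pectin genes (0.24). The cellulose and matrix polysaccharide list was not called (9 higher, 3 lower of 31, adjusted p = 0.31), but its member CSLF6 (Os08g0160500), a mixed-linkage glucan synthase, rose by 0.97 ± 0.14. Its members Os10g0578200 and Os07g0252400 rose by 0.67 ± 0.10 and 0.64 ± 0.11.

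The jasmonate synthesis and signalling list was not called in wild type with salt (5 higher, 10 lower of 32, or 5 and 11 adjusted over the list alone, adjusted p = 0.24). The names of this list's members are those on the array and alone do not show that a gene acts in jasmonate synthesis. The brightest probe of a lipoxygenase (Os03g0699700) fell with salt to background (-3.20 ± 0.15), while its other tested probe stood at -0.09 (-1.65 as the mean of its probes). Lipoxygenase L-2 (Os03g0738600) fell (-0.88 ± 0.22). An oxophytodienoate reductase (Os06g0215600) rose by 1.66 ± 0.17. Nor was the list of defence proteins called (59 higher, 36 lower of 195, adjusted p = 0.36). Without loci matched by part of a name, 25 of 114 were higher and 23 lower. In that list the chitinase Os01g0660200 fell (-3.30 ± 0.14) and the chitinase homologue Os11g0702100 rose by 2.65 ± 0.21. With Agilent's processed signals, 5 of the 40 named values were over 1.5 times as large, among them PR1a (-5.77) and EXPA18 (4.22).

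The second comparison asked how rss3 root tips differ from wild type without salt. By camera with its preset correlation, lists of jasmonate, defence, lignin and nutrient and metal transport genes were higher in the mutant, and those of ribosomal proteins, histones and mitosis lower. With an estimated correlation 0 of 26 lists were called (smallest adjusted p = 0.34). The largest rises were a cyclophilin (Os10g0154700, 4.03 ± 0.16, above background on only 1 wild-type array), the pepsin-family peptidase Os02g0720900 (3.99 ± 0.17), the probenazole-inducible defence protein PBZ1 (Os12g0555300, 3.90 ± 0.37), a cytochrome P450 (Os04g0178400, 3.79 ± 0.29), a lipase (Os05g0153300, 3.75 ± 0.13) and catalase A (Os02g0115700, 3.71 ± 0.28). The deepest falls were a lipid transfer protein (Os01g0814100, -3.31 ± 0.16), a late embryogenesis abundant protein (Os01g0968100, -2.43 ± 0.16), a carbohydrate-binding protein (Os01g0893700, -2.20 ± 0.07), a SKP1 family protein (Os07g0625400, -2.14 ± 0.19), an ABC protein (Os10g0432200, -2.11 ± 0.28) and a Bowman-Birk proteinase inhibitor (Os01g0127600, -2.06 ± 0.09). The tested probes of Os02g0720900 ranged from 2.33 to 3.99, and those of Os01g0814100 from -3.31 to -2.09. Of 31352 probes, 6454 were higher and 5087 lower in rss3 (11541 in all), of which 954 and 147 changed at least 2-fold.

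Jasmonate genes were higher in rss3 without salt in 15 of 32 measured loci and lower in 0 (16 and 0 adjusted over the list alone). The median change was 0.29 and camera gave an adjusted p of 0.0001, which was 0.43 with an estimated correlation. The gene named allene oxide synthase (Os02g0218800) was 2.61 ± 0.12 higher and the lipoxygenase Os03g0699700 1.64 ± 0.15 (1.07 as the mean of its probes). A protein with the ZIM domain of the jasmonate repressors (Os07g0615200) was 1.27 ± 0.15 higher. Defence proteins were higher in 76 of 195 loci and lower in 25 (median 0.18, adjusted p = 0.00015, or 0.34 with an estimated correlation). That list holds loci matched by part of a name, such as nicotianamine synthases and methyltransferases. Without them 51 of 114 were higher and 13 lower. WRKY and NAC transcription factors were higher in 33 of 92 loci and lower in 4 (median 0.17, adjusted p = 0.00024, or 0.36 with an estimated correlation). The jasmonate and cell wall topics were chosen knowing that the study of this mutant concerns jasmonate and root elongation.

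Of the cell wall lists, peroxidases were higher in rss3 in 51 of 96 loci and lower in 9 (median 0.49, adjusted p = 1.4e-07, or 0.34 with an estimated correlation), including Os07g0676900 (3.08 ± 0.24) and peroxidase 1 (Os05g0162000, 2.88 ± 0.18). Lignin genes were higher in 24 of 49 loci and lower in 1 (median 0.29, adjusted p = 6.3e-06, or 0.36 with an estimated correlation), with caffeic acid methyltransferase Os08g0157500 at 3.62 ± 0.22, phenylalanine ammonia-lyase Os05g0427400, the entry to the pathway, at 2.88 ± 0.30 and cinnamoyl-CoA reductase Os08g0441500 at 2.48 ± 0.17. Expansins and xyloglucan enzymes were higher in 34 of 78 loci and lower in 14 (median 0.20, adjusted p = 0.0034, or 0.39 with an estimated correlation), with EXPA5 (Os01g0248900) at 2.31 ± 0.16 and EXPA19 at 2.08 ± 0.24. Pectin enzymes and extensins were higher in 34 of 98 and lower in 16 (median 0.13, adjusted p = 0.030, or 0.43 with an estimated correlation). The pectin call was lost without wild type 0 mM replicate 2 (0.09) or rss3 0 mM replicate 3 (0.10), with median centring (0.16), with no filter on dim probes (0.05) and with the mean of all probes of a locus (0.12). The cellulose list was not called (12 higher, 2 lower of 31, adjusted p = 0.14). In it, the cellulose synthase Os10g0467800, known for secondary walls, was 2.14 ± 0.31 higher in rss3, against background in wild type without salt.

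Genes of nitrate, phosphate and metal transport, a list made as a marker of mature root, were higher in rss3 without salt in 24 of 49 loci and lower in 2 (median 0.28, adjusted p = 5.5e-05, or 0.34 with an estimated correlation). Those named by the largest change make the iron chelator precursors of grasses: a nicotianamine synthase (Os07g0689600, 3.39 ± 0.10), nicotianamine aminotransferase (Os02g0302700, 1.86 ± 0.10) and the nicotianamine synthase Os03g0307300 (1.60 ± 0.44, against background in wild type). The other list of mature root cell types (Casparian strip, suberin and root hair) had 8 of 25 loci higher and 0 lower and was not called (median 0.12, adjusted p = 0.061), while lists of division and ribosomal genes were lower. The mix of cell types in the 1 mm tips was not measured. In each comparison a different mix cannot be told apart from regulation within cells. Aquaporins were higher in 7 of 11 loci and lower in 3 (median 0.69, adjusted p = 0.015, or 0.43 with an estimated correlation). Ribosomal proteins were lower in 71 of 269 loci and higher in 6 (median -0.09, adjusted p = 6.3e-06, or 0.43 with an estimated correlation), led by the near-identical S9 genes Os07g0628300 (-1.15 ± 0.15) and Os03g0379500 (-0.999 ± 0.14), whose probes may share signal. Histones were lower in 18 of 46 loci and higher in 2 (median -0.15, adjusted p = 5.5e-05, or 0.43 with an estimated correlation), with the H2A gene Os03g0721900 at -0.59 ± 0.09. Translation factors were lower in 27 of 72 loci and higher in 4 (median -0.11, adjusted p = 0.00025, or 0.34 with an estimated correlation). Mitosis genes were lower in 37 of 96 loci and higher in 10 (median -0.15, adjusted p = 0.0010, or 0.43 with an estimated correlation), and DNA replication genes lower in 11 of 49 and higher in 1 (median -0.06, adjusted p = 0.025, or 0.36 with an estimated correlation). Median centring ended the calls for ribosomal proteins (0.03), histones (-0.03), translation factors (-0.02) and DNA replication (0.01), the first and the last with a turned sign that was absent relative to the median of all probes. The DNA replication call also ended with no filter on dim probes (-0.05). With Agilent's processed signals, 7 of the 39 named values were over 1.5 times as large, among them the cyclophilin (7.08) and Os07g0689600 (6.29).

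The third comparison asked what salt does in rss3. By camera with its preset correlation, lists of lignin, peroxidase, late embryogenesis and detoxification genes rose in the mutant and ribosomal proteins fell, the peroxidase and detoxification calls ending under some alternatives. With an estimated correlation 0 of 26 lists were called (smallest adjusted p = 0.79). The largest rises were a glycine-rich cell wall protein (Os10g0450800, 4.32 ± 0.29), the peroxidase Os12g0112000 (3.74 ± 0.23), a transferase (Os11g0507200, 3.54 ± 0.35), an isoflavone reductase-like protein (Os01g0106400, 3.34 ± 0.37), the lectin Os03g0245500 (3.19 ± 0.50) and a harpin-induced domain protein (Os02g0538700, 3.15 ± 0.36, or 1.74 as the mean of its probes). The deepest falls were the germin Os08g0231400 (-5.08 ± 0.18), the chitinase Os01g0660200 (-4.98 ± 0.14) and the peptidases Os10g0537800 (-4.76 ± 0.38) and Os10g0538200 (-3.92 ± 0.31). In all, 7838 probes were higher and 4509 lower with salt (12347 of 31352), of which 1165 and 216 changed at least 2-fold.

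Lignin genes rose with salt in rss3 in 32 of 49 loci and fell in 4 (median 0.52, adjusted p = 3.4e-05, or 0.79 with an estimated correlation). A 4-coumarate-CoA ligase-like gene (Os04g0683700) rose by 2.73 ± 0.25, cinnamoyl-CoA reductase Os08g0441500 by 2.64 ± 0.17 and a laccase (Os01g0842500) by 2.51 ± 0.26. Late embryogenesis, dehydrin and abscisic acid response genes, which mark water deficit, rose in 30 of 56 loci and fell in 3 (median 0.28, adjusted p = 0.0023, or 0.79 with an estimated correlation), such as Os01g0968100 (2.52 ± 0.16) and the LEA3 family gene Os01g0314800 (2.17 ± 0.28). For salt in wild type, without members matched by accident, 20 of 55 loci of this list rose and 8 fell (camera adjusted p = 0.051). Its interaction was not called (camera adjusted p = 0.43), so the call does not show a response particular to rss3. Peroxidases rose in 49 of 96 loci and fell in 14 (median 0.43, adjusted p = 0.0060, or 0.79 with an estimated correlation), a call that ended among probes well above background on all 12 arrays (median 0.24). Oxidative stress and detoxification genes rose in 62 of 157 loci and fell in 17 (median 0.13, adjusted p = 0.043, or 0.79 with an estimated correlation), with catalase 2 (Os03g0131200) at 2.86 ± 0.09 and catalase A at 2.46 ± 0.28. This call was lost without rss3 0 mM replicate 2 (0.12) or 3 (0.13). Ribosomal proteins fell in 71 of 269 loci and rose in 11 (median -0.09, adjusted p = 7.3e-06, or 0.79 with an estimated correlation), although the S9 genes rose (Os07g0628300 by 1.06 ± 0.15, Os03g0379500 by 0.83 ± 0.14).

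The jasmonate list was not called for salt in rss3 (9 higher, 6 lower of 32, or 11 and 6 adjusted over the list alone, adjusted p = 0.70). The lipoxygenase Os03g0699700 fell (-3.24 ± 0.15, or -2.01 as the mean of its probes), the reductase Os06g0215600 rose by 2.37 ± 0.17, and a ZIM domain gene (Os03g0180900) rose from background by 2.87 ± 0.62, with log2 ratios of 4.43, 1.04 and 3.63 on the 3 arrays with salt. Defence proteins (74 higher, 39 lower of 195, adjusted p = 0.43, or 36 and 27 of 114 without loci matched by part of a name), expansins (33 and 13 of 78, adjusted p = 0.11), pectin enzymes (38 and 10 of 98, adjusted p = 0.11) and the cellulose list (7 and 2 of 31, adjusted p = 0.78) were not called either. Their members included a glucanase (Os05g0495900, 2.93 ± 0.25), an endochitinase (Os06g0726100, -2.85 ± 0.14), an arabinogalactan protein (Os01g0159200, 2.47 ± 0.20) and the secondary-wall cellulose synthases Os10g0467800 (2.52 ± 0.31) and Os01g0750300 (2.31 ± 0.19). With Agilent's processed signals, 5 of the 40 named values were over 1.5 times as large, among them the germin (-7.77).

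The fourth comparison asked how rss3 differs from wild type when both grow with salt. By camera with its preset correlation, lists of jasmonate, lignin, defence, and WRKY and NAC genes were higher in the mutant. With an estimated correlation 0 of 26 lists were called (smallest adjusted p = 0.63). The largest differences were catalase A (Os02g0115700, 5.44 ± 0.28), cinnamoyl-CoA reductase (Os08g0441500, 5.08 ± 0.17), a chlorophyll a/b binding protein (Os09g0346500, 4.31 ± 0.31), a plastocyanin-like protein (Os06g0218600, 4.13 ± 0.38), the cyclophilin Os10g0154700 (4.06 ± 0.16) and the cellulose synthase Os10g0467800 (4.03 ± 0.31). Lower in the mutant were the lipid transfer protein Os01g0814100 (-4.85 ± 0.16), the carbohydrate-binding protein Os01g0893700 (-2.98 ± 0.07), peroxidase 27 (Os07g0531400, -2.78 ± 0.12), the root-specific protein RCc2 (Os10g0551800, -2.57 ± 0.21) and a phytosulfokine precursor (Os03g0232400, -2.45 ± 0.11), a growth peptide. The tested probes of Os01g0814100 ranged from -4.85 to -3.40. Of 31352 probes, 7537 were higher and 4058 lower in rss3 (11595 in all), of which 1675 and 231 changed at least 2-fold, or 87.9% higher. Over all changed probes rises made up 65.0%, but 45.3% with processed signals and 39.1% with Cy5 alone.

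Jasmonate genes were higher in rss3 with salt in 22 of 32 loci and lower in 1, over all genes and adjusted over the list alone alike (median 0.60, adjusted p = 2.4e-06, or 0.63 with an estimated correlation). ZIM domain genes were among the largest (Os03g0180900, 2.87 ± 0.62 but above background on only 1 wild-type array with salt, so of uncertain size, Os09g0439200, 1.84 ± 0.14, and Os07g0615200, 1.83 ± 0.15). Lignin genes were higher in 31 of 49 loci and lower in 2 (median 0.56, adjusted p = 2.4e-06, or 0.63 with an estimated correlation), including a laccase (Os01g0842500, 3.39 ± 0.26, against background in wild type) and phenylalanine ammonia-lyase Os02g0627100 (3.33 ± 0.31, above background on only 1 wild-type array). WRKY and NAC factors were higher in 47 of 92 loci and lower in 4 (median 0.28, adjusted p = 4.4e-06, or 0.63 with an estimated correlation), such as the NAC gene Os01g0672100 (2.34 ± 0.21) and the defence regulator WRKY45 (Os05g0322900, 2.00 ± 0.18). Defence proteins were higher in 89 of 195 loci and lower in 20 (median 0.23, adjusted p = 9.8e-05, or 0.63 with an estimated correlation), and without loci matched by part of a name in 58 of 114 and lower in 11. Examples are PBZ1 (3.73 ± 0.37), a chitinase (Os10g0542900, 3.61 ± 0.35) and a dirigent protein (Os07g0636800, 3.61 ± 0.15).

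Peroxidases differed both ways with salt, 55 of 96 higher in rss3 and 21 lower (median 0.61, adjusted p = 0.00031, or 0.64 with an estimated correlation). Metal and nutrient transport genes were higher in 27 of 49 loci and lower in 7 (median 0.32, adjusted p = 0.0018, or 0.63 with an estimated correlation), led by the nicotianamine synthases Os03g0307200 (3.03 ± 0.55) and Os03g0307300 (2.87 ± 0.44), both at background in wild type, and Os07g0689600 (2.57 ± 0.10). Histones were higher in 23 of 46 loci and lower in 1 (median 0.17, adjusted p = 0.00018, or 0.64 with an estimated correlation), with the H4 gene Os09g0433600 at 0.52 ± 0.05. This call, and that of Os09g0433600, ended with median centring (list median 0.09). The lists of expansins (30 higher, 20 lower of 78, adjusted p = 0.85), pectin enzymes (42 and 18 of 98, adjusted p = 0.082), cellulose synthesis (11 and 6 of 31, adjusted p = 0.58) and ribosomal proteins (12 and 10 of 269, adjusted p = 0.30) were not called. Of the cellulose list, the secondary-wall gene Os01g0750300 was 2.64 ± 0.19 higher in rss3, beside Os10g0467800. With Agilent's processed signals, 9 of the 39 named values were over 1.5 times as large, among them the phytosulfokine precursor (-3.91), and rises made up 46.3%, 44.0%, 46.4% and 45.3% of the changed probes in the 4 comparisons, against 55.4%, 55.9%, 63.5% and 65.0% with loess.

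**Figure D2:**
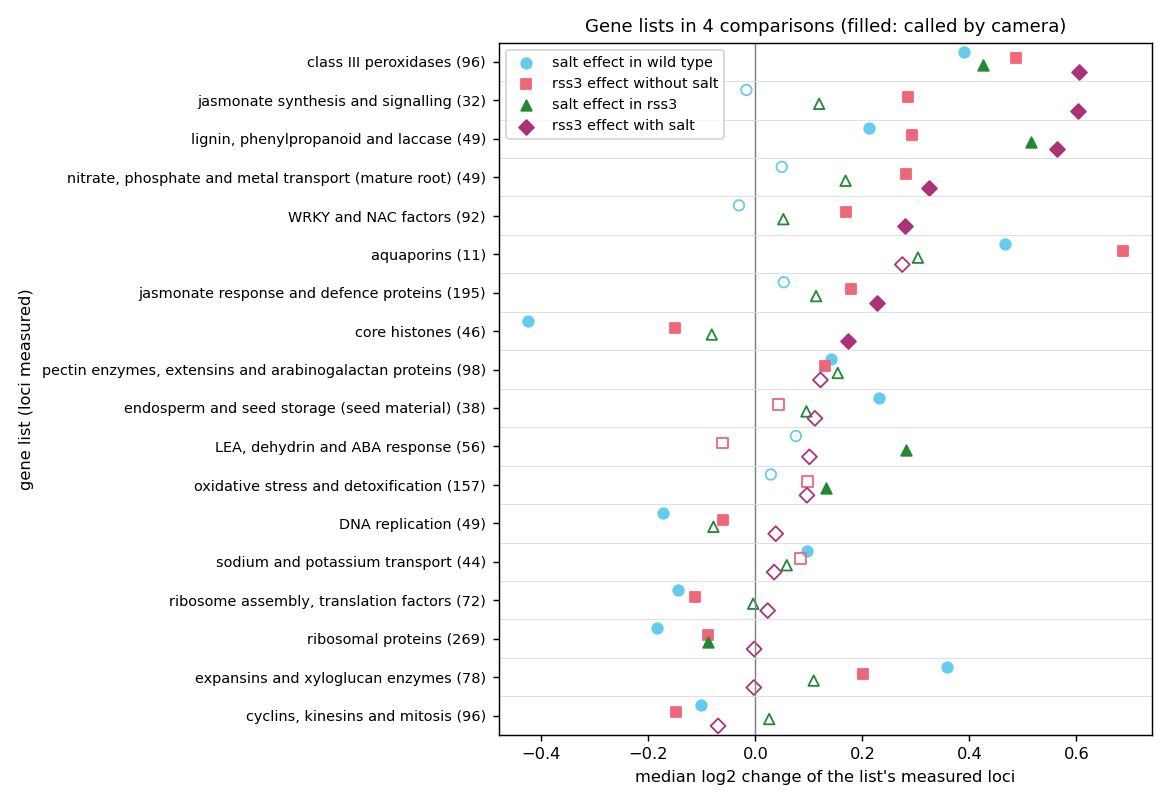
The horizontal axis gives the median log2 change of each gene list (vertical axis, with its number of measured loci) in the 4 comparisons between groups, with filled symbols where camera called the list with its preset correlation. Jasmonate genes lie at 0.29 and 0.60 in the rss3 effects and at -0.02 and 0.12 in the salt effects, and histones at -0.42 for salt in wild type and -0.08 in rss3. Among called medians, median centring turns the sign of mitosis (salt in wild type), DNA replication and ribosomal proteins (rss3 without salt), and the jasmonate median for salt in wild type is 0.00.

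**Figure D3:**
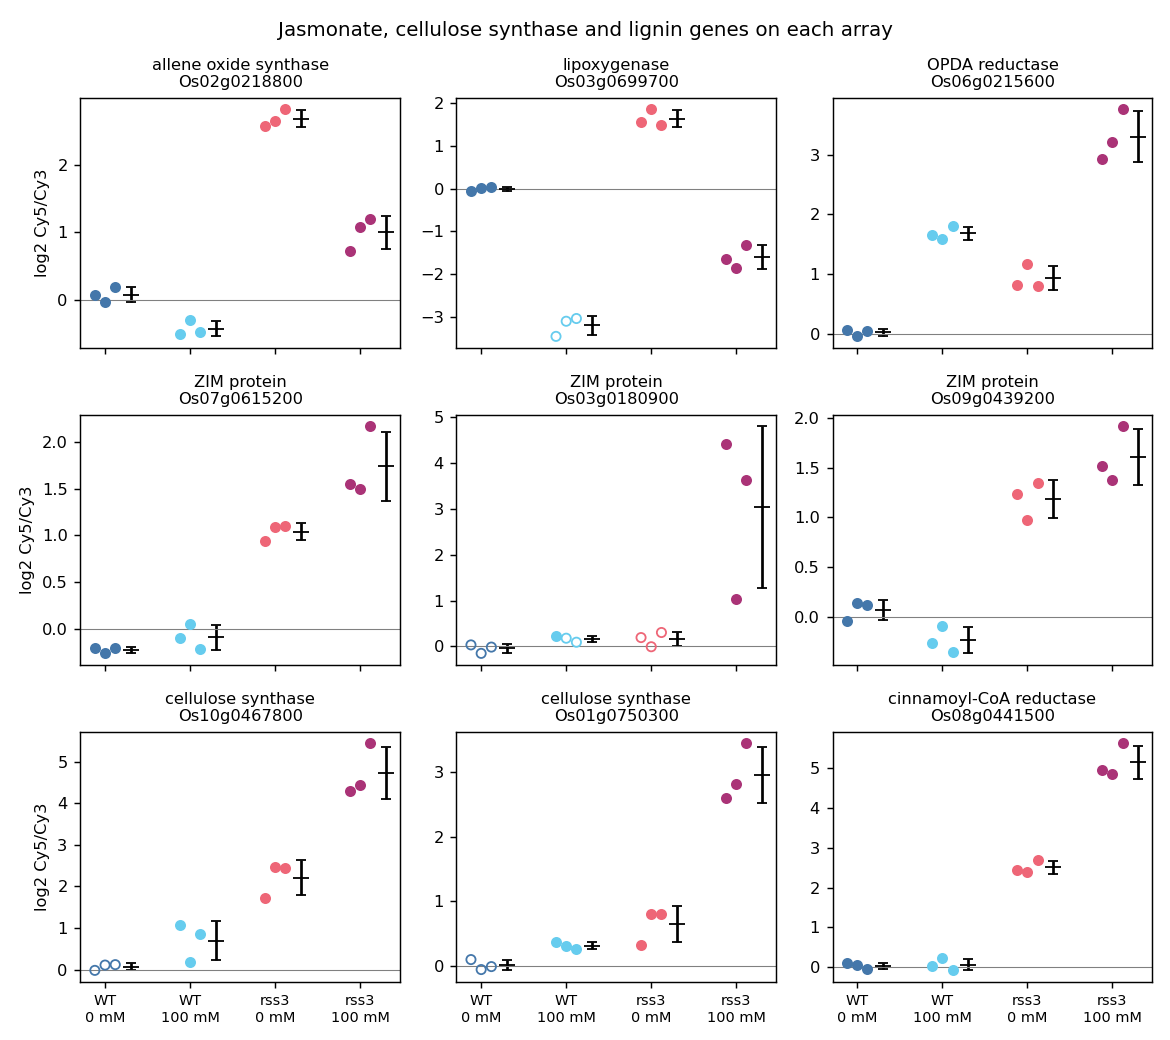
Each point is the log2 ratio of Cy5 (sample) over Cy3 (wild-type 0 mM reference) on 1 array, by group, for jasmonate, cellulose synthase and lignin genes, with the mean and SD of 3 arrays in black and open points where Cy5 was not well above background. The vertical scale differs between panels. The lipoxygenase is drawn by its brightest probe, and its other tested probe changed by -0.09 for salt in wild type. Allene oxide synthase is highest in rss3 without salt, and cinnamoyl-CoA reductase and the cellulose synthases are highest in rss3 with salt on each of the 3 arrays.

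The fifth comparison asked whether salt acts differently in rss3 than in wild type, tested as the interaction. By camera with its preset correlation, lists of histones, translation factors and ribosomal proteins had positive interactions, and those of expansins and aquaporins negative ones. With an estimated correlation 0 of 26 lists were called (smallest adjusted p = 0.52). Of the 8 lists called with the preset, 4 were also called by fry in the same direction. Salt raised in rss3, beyond its effect in wild type, the glycine-rich wall protein Os10g0450800 (3.58 ± 0.40), a MtN3 family protein (Os11g0508600, 3.02 ± 0.35, not above background in wild type) and the harpin-induced domain protein Os02g0538700 (2.65 ± 0.51, or 1.48 as the mean of its probes). The chlorophyll a/b binding protein Os09g0346500 (2.67 ± 0.44) owed more of its interaction to a fall in wild type (-1.79 ± 0.31) than to its rise in rss3 (0.88 ± 0.31). In the other direction were EXPA19 (Os03g0428700, -2.99 ± 0.34), the intrinsic protein MipE (Os04g0233400, -2.73 ± 0.35), peroxidase 12 (Os01g0962700, -2.43 ± 0.28) and the peptidase Os02g0720900 (-2.36 ± 0.24). The tested probes of peroxidase 12 ranged from -2.43 to -1.51, and those of the peptidase from -2.36 to -1.44. The interaction passed for 4478 of 31352 probes, 2610 positive and 1868 negative (58.3% positive, but 48.7% with median centring and 47.5% with Cy5 alone). In the authors' table the interaction passed for 0 probes after Benjamini-Hochberg and for 2992 unadjusted, against 3883 after Benjamini-Hochberg when the authors' kind of test was run on the values used here. Of the positive ones, 1275 were called higher with salt in rss3 and not called in wild type, and 732 were called lower in wild type and not called in rss3. Of the negative ones, 795 were called higher in wild type and not called in rss3. The count fell by more than 1.5 times without wild type 0 mM replicate 1 (2828) or 2 (2852) or rss3 0 mM replicate 2 (2925), and with median centring (1432).

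Histones had the strongest interaction of the lists. Of 46 loci 28 were positive and 1 negative (34 and 1 adjusted over the list alone), with a median of 0.36 and an adjusted p of 4.3e-13, which was 0.52 with an estimated correlation. The H2B genes Os05g0574300 (0.65 ± 0.08) and Os01g0152300 (0.59 ± 0.09) and the H4 gene Os09g0433600 (0.59 ± 0.07) led it, although median centring ended each of these 3 calls (0.40, 0.36 and 0.36) and Cy5 alone that of Os05g0574300 (0.29). Translation factors were positive in 20 of 72 loci and negative in 0 (median 0.14, adjusted p = 0.00026, or 0.52 with an estimated correlation), and ribosomal proteins in 33 and 0 of 269 (median 0.10, adjusted p = 0.0014, or 0.85 with an estimated correlation). Median centring ended both calls. It gave -0.03 for translation factors, which stayed positive relative to the median of all probes (0.05), and -0.15 for ribosomal proteins, which were negative relative to it too (-0.07). The interaction of ribosomal proteins was 0.17 and 0.15 on slides 1 and 2 but -0.012 on slide 3. DNA replication genes were positive in 3 of 49 loci and negative in 0 (median 0.11, adjusted p = 0.024, or 0.60 with an estimated correlation), a call lost without rss3 100 mM replicate 1 or 2 (0.11 without either), with Cy5 alone (0.04), with median centring (0.03) and with no filter on dim probes (0.10). The 3 were a reverse transcriptase domain protein (Os08g0164800, 0.82 ± 0.20), a domain typical of retroelements and not of replication, DNA polymerase V (Os02g0135700, 0.37 ± 0.07) and the replication clamp PCNA (Os02g0805200, 0.36 ± 0.08). Median centring ended these 3 calls (0.76, 0.19 and 0.15), and Cy5 alone that of DNA polymerase V (0.26).

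**Figure D4:**
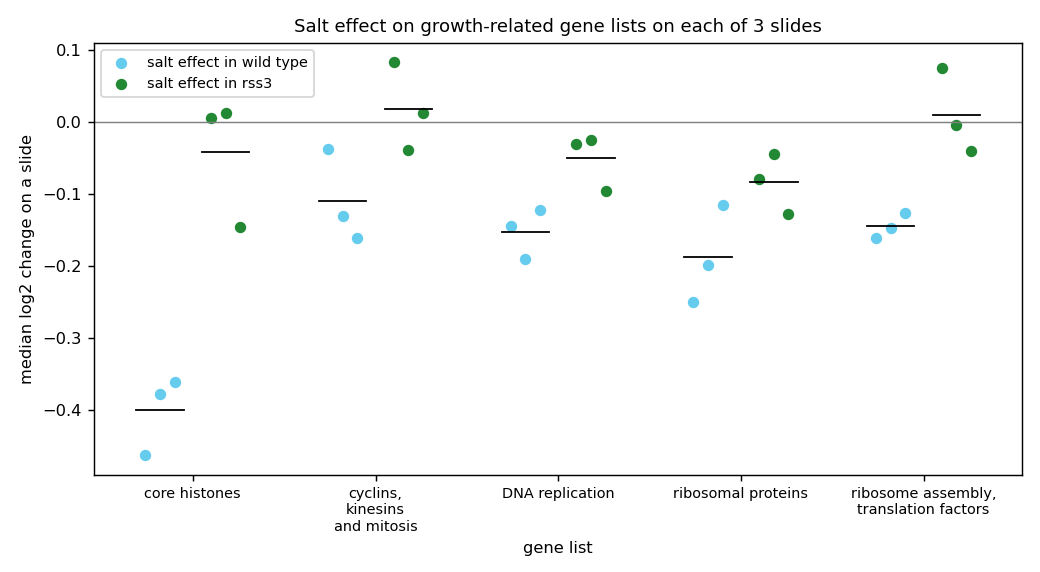
Each point is the median log2 change of a gene list (horizontal axis) on 1 of the 3 slides for the salt effect in wild type or in rss3, and the black bars are means over the slides. Histones lie at -0.46, -0.38 and -0.36 in wild type and at 0.01, 0.01 and -0.15 in rss3. With median centring in place of loess, the interaction of ribosomal proteins has the other sign, also relative to the median of all probes, and that of translation factors only in absolute terms.

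Expansins and xyloglucan enzymes had a negative interaction in 20 of 78 loci and a positive one in 11 (median -0.09, adjusted p = 0.0073, or 0.74 with an estimated correlation), led by EXPA19 and EXPA18 (Os03g0155900, -1.91 ± 0.27). Of 11 aquaporins 5 were negative and 0 positive (median -0.35, adjusted p = 0.011, or 0.77 with an estimated correlation), with TIP2.1 (Os02g0658100) at -1.61 ± 0.37. The aquaporin call was lost without rss3 100 mM replicate 1 (-0.18). The expansin, aquaporin and peroxidase calls ended with Cy5 alone (-0.07, -0.24 and -0.12). Sodium and potassium transport genes were negative in 7 of 44 loci and positive in 0 (median -0.04, adjusted p = 0.025, or 0.52 with an estimated correlation). Their call was lost without wild type 100 mM replicate 1 (-0.05), rss3 100 mM replicate 1 (-0.02) or rss3 0 mM replicate 3 (-0.03), and with no filter on dim probes (-0.03). Peroxidases went both ways, 26 of 96 negative and 15 positive (median -0.09, adjusted p = 0.025, or 0.85 with an estimated correlation), a call lost without wild type 0 mM replicate 2 (-0.04), rss3 0 mM replicate 3 (-0.08) or rss3 100 mM replicate 1 (-0.06), with median centring (-0.22) and with no filter on dim probes (-0.03).

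The jasmonate list had an interaction in 5 positive and 2 negative of 32 loci (11 and 2 adjusted over the list alone) and was not called (median 0.17, adjusted p = 0.066). Allene oxide synthase had a negative interaction (-1.17 ± 0.17) and lipoxygenase 1 (Os03g0700400) a positive one (1.07 ± 0.24). The defence (20 positive, 16 negative of 195, adjusted p = 0.68), pectin (11 and 12 of 98, adjusted p = 0.59) and cellulose lists (3 and 1 of 31, adjusted p = 0.68) were not called. Their members with the largest interactions were the glucanase Os05g0495900 (2.40 ± 0.36), the arabinogalactan protein Os01g0159200 (2.57 ± 0.29), an extensin domain protein (Os01g0899700, 2.45 ± 0.29) and the cellulose synthases Os01g0750300 (2.00 ± 0.26) and Os10g0467800 (1.89 ± 0.44). Both synthases and the arabinogalactan protein were at background in wild type without salt, so the size of their interactions is uncertain. Agilent's processed signals ended 10 of the 40 named calls, among them those of the glucanase (1.74) and both cellulose synthases (1.84 and 0.28), and made 5 values over 1.5 times as large, among them EXPA18 (-3.33). The false share among calls was 5.03% in simulated data with 200 changed probes and independent noise. It does not give the false share of the real interaction calls.

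The responses were also compared across probes, which are not independent replicates. The salt effects in wild type and rss3, which share no arrays, correlated at r = 0.62 (Spearman's rho 0.57). Of the probes, 3529 were higher with salt in both genotypes and 2021 lower in both, where independent calls would give 1474 and 684, and 438 were called in opposite directions (2036 if independent). The rss3 effects without and with salt correlated at r = 0.69 (rho 0.61), with 4222 probes higher in both, 1875 lower in both and 313 opposite (1552, 658 and 2058 if independent). The salt effect in wild type and the rss3 effect without salt correlated at r = 0.28 (rho 0.29), but both use the wild-type 0 mM arrays, which alone gave a mean r of 0.50 in simulated data with no effects. Their covariance was 0.046, against 0.0058 in those simulations.

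Each replicate number was a slide that held 1 array of each group, and the changes were recomputed on each slide. Between slides, the changes correlated across probes at r = 0.80 to 0.87 for salt in wild type, 0.85 to 0.90 for rss3 without salt, 0.77 to 0.84 for salt in rss3, 0.78 to 0.86 for rss3 with salt and 0.56 to 0.63 for the interaction. Of the called probes, 99.8%, 99.8%, 98.6%, 98.7% and 99.8% had the same sign on all 3 slides, in that order. The probes were called on these same arrays, so these shares are no independent test. A group kept its position within the slide on each slide, so position and group cannot be told apart.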

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

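The tests of a larger share of dividing cells, of shoot tissue, and of other splits with the shared salt effect removed were written after the results were seen. The results in this part stand out because the salt effect differed between wild type and rss3 by a test of the interaction. It passed for 4478 probes. Groups of 3 arrays are too small for a test of single arrays that lie apart.

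Among the lists, the median interaction was 0.36 for core histones, 0.14 for translation factors, 0.11 for DNA replication, 0.10 for ribosomal proteins (-0.15 with median centring), -0.038 for sodium and potassium transport, -0.089 for peroxidases, -0.086 for expansins and -0.35 for aquaporins. These were calls by camera with its preset correlation, and with an estimated correlation 0 of 26 lists were called (smallest adjusted p = 0.52). Fry called 5 lists here, and only 4 of the 8 camera calls were among them in the same direction. Cy5 alone ended the calls of DNA replication (0.042), aquaporins (-0.24), peroxidases (-0.12) and expansins (-0.072). Leaving out an array ended those of DNA replication (0.11 without rss3 100 mM replicate 1 or 2), aquaporins (-0.18 without rss3 100 mM replicate 1), peroxidases (without wild type 0 mM replicate 2, -0.037, rss3 0 mM replicate 3, -0.084, or rss3 100 mM replicate 1, -0.063) and sodium and potassium transport (without wild type 100 mM replicate 1, -0.052, rss3 0 mM replicate 3, -0.032, or rss3 100 mM replicate 1, -0.024). The largest positive interactions were those of Os10g0450800 (glycine-rich wall protein, 3.58), Os11g0508600 (MtN3, 3.02), Os09g0346500 (chlorophyll a/b binding, 2.67), Os03g0307200 (nicotianamine synthase, 2.67), Os03g0368900 (peroxidase, 2.65) and Os02g0538700 (harpin-induced domain, 2.65). The largest negative ones were those of Os03g0428700 (EXPA19, -2.99), Os04g0178400 (cytochrome P450, -2.82), Os04g0233400 (MipE, -2.73), Os01g0962700 (peroxidase 12, -2.43), Os02g0720900 (peptidase, -2.36) and Os02g0285300 (DREPP, -2.33).

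Jasmonate and defence members were Os02g0218800 (-1.17), Os03g0700400 (1.07), Os09g0439200 (0.72), Os05g0495900 (2.40) and Os03g0399800 (jacalin, 1.99). Wall members were Os03g0155900 (EXPA18, -1.91), Os06g0696600 (xyloglucan transferase, 1.43), the cellulose synthases Os01g0750300 (2.00) and Os10g0467800 (1.89), and Os10g0341700 (0.75) of the cellulose and matrix polysaccharide list. Further ones were the arabinogalactan and extensin-type proteins Os01g0159200 (2.57), Os01g0899700 (2.45) and Os08g0108300 (2.33). Growth genes were the histones Os05g0574300 (0.65), Os01g0152300 (0.59) and Os09g0433600 (0.59), the translation and ribosome assembly genes Os02g0300700 (1.03), Os01g0723000 (0.96) and Os07g0475800 (0.64), the ribosomal proteins Os07g0628300 (0.75), Os03g0379500 (0.69) and Os05g0292500 (0.65), and the replication list members Os08g0164800 (0.82), Os02g0135700 (0.37) and Os02g0805200 (0.36). Aquaporins were Os02g0658100 (-1.61), Os04g0521100 (-1.08) and Os02g0666200 (-0.85).

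Median centring ended the call for 13 of these 40 genes, 6 of them over 1.5 times smaller: Os05g0574300 (0.40), Os01g0152300 (0.36), Os09g0433600 (0.36), Os07g0475800 (0.42), Os02g0135700 (0.19) and Os02g0805200 (0.15). The others were Os08g0164800 (0.76), Os09g0439200 (0.70), Os10g0341700 (0.60), Os07g0628300 (0.58), Os03g0379500 (0.56), Os05g0292500 (0.48) and Os04g0521100 (-1.24). Cy5 alone ended 4 calls, Os05g0574300 (0.29), Os02g0135700 (0.26), Os10g0341700 (0.58) and Os07g0628300 (0.72), and the mean of all probes those of Os02g0300700 (0.61) and Os03g0307200 (2.36). A replicate block and a slide block each ended 1 of the 40 calls. Processed signals ended 10 calls, Os01g0723000 (0.49), Os04g0178400 (-1.37), Os10g0467800 (0.28), Os05g0495900 (1.74), Os01g0750300 (1.84), Os03g0307200 (4.33), Os03g0368900 (3.73), Os06g0696600 (2.31), Os03g0379500 (0.74) and Os07g0628300 (0.78), and made 3 values that kept their call over 1.5 times as large, Os04g0521100 (-3.69), Os03g0155900 (-3.33) and Os08g0108300 (4.51).

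Leaving out 1 array ended the call for 7 of these 40 genes. It ended for Os01g0723000 without wild type 0 mM replicate 2 (0.89), and for Os02g0666200 without wild type 0 mM replicate 2 (-0.79) or rss3 0 mM replicate 2 (-0.76). It ended for Os09g0439200 without wild type 100 mM replicate 1 or 3, wild type 0 mM replicate 2 or 3, or rss3 0 mM replicate 2 (0.62 to 0.71). For Os04g0521100 it ended without wild type 100 mM replicate 1 or 2, wild type 0 mM replicate 2 or 3, rss3 0 mM replicate 2 or 3, or rss3 100 mM replicate 1 (-1.12 to -0.93). For Os03g0307200 it ended without any 1 array but rss3 100 mM replicate 1 or 3 (2.43 to 2.87). For Os07g0628300 it ended without any 1 array but wild type 100 mM replicate 1, wild type 0 mM replicate 2 or rss3 100 mM replicate 2 (0.63 to 0.79), and for Os03g0379500 the exceptions were these and rss3 0 mM replicate 3 (0.57 to 0.72).

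Other splits of the arrays were counted for each number of changed probes. For the 4 comparisons of 3 arrays with 3, 1 of 10 splits gave as many as the real one (10648, 11541, 12347 and 11595) and the highest of the others gave 0, but 10 splits are too few for a share under 0.05. Each other split mixed the real groups and so put their difference into the residuals. These counts therefore do not decide about chance. For the interaction, 2 of 100 splits of the salt labels within each genotype gave as many as the real 4478, and the highest other gave 15408. It had the salt labels mirrored in 1 genotype, which turns the difference of the salt effects into their sum, so it points to the shared salt effect as a structure of the samples. Such splits also put the shared salt effect into the residuals, so this count does not decide whether the interaction arose by chance. With the shared salt effect subtracted first, 1 of 100 splits gave as many as the real 4478 and the highest other gave 0, a share under 0.05. That effect was estimated with the real labels, so the mirrored split could show no interaction. The other splits still carried the interaction in their residuals, so this count does not decide about chance either.

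The first pattern weighed is that rises outnumbered falls in rss3 with salt (87.9% of the probes changed at least 2-fold). Among probes well above background on all 12 arrays the share was 85.2%, which argues against dim probes in wild type as the whole cause. Without the bright array, rss3 100 mM replicate 3, it was 86.6%, and the lowest share over the other 3 scalings was 76.2%, which argue against that array and against scaling. Over all changed probes, however, the share was 65.0% with loess but 45.3% with processed signals, so the pattern holds for the larger changes. The share was 86.6% without salt as well, so salt is not needed for it. Rises of at least 2-fold also outnumbered falls for salt in wild type (754 and 241) and for salt in rss3 (1165 and 216), so the excess is not particular to the mutant. No biological explanation was tested.

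The second pattern is that histones fell less with salt in rss3. Their median interaction was 0.38 without the bright array and at least 0.17 on each slide, which argue against that array and a single slide. A larger share of dividing cells stays open. It would raise mitosis and replication genes alike, and the smallest gap between the histone median and theirs on a slide was -0.028. Position on the slide cannot be told apart from group, and an effect of rss3 on the cell cycle stays open as well.

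The third pattern is a chlorophyll a/b binding gene (Os09g0346500) that was 4.31 higher in rss3 with salt. Shoot tissue would bring all abundant photosynthesis transcripts. In the list without members matched by accident, the median of the other 55 genes was 0.09 (20 higher, 4 lower, from -1.84 to 1.72). Of these, 43 were above background in wild type without salt. The Rubisco small subunit Os11g0298400 stood at 0.12, but it was not abundant. Its log2 Cy5 signal in rss3 with salt was 8.65, against 12.23 for Os09g0346500. The list also holds chaperonins and loci dim in rss3 with salt, which pull its median down. These values therefore do not decide whether shoot tissue was the source. The lowest value was that of another chlorophyll a/b binding gene (Os01g0720500). Among the higher genes were plastocyanin (1.72), a type III chlorophyll a/b-binding protein (1.06) and photosystem I subunit II (0.84). A smaller rise shared by part of the photosynthesis genes therefore stays open. The lowest of the locus's 5 other probes stood at 1.09, which argues against a single faulty probe. A change in this gene in the mutant root may remain, as a hypothesis.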

How the results depend on the processing

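Of 198 named changes past the threshold, 160 kept their call under each alternative that gave them a value, and none reversed. Only 144 of the 198 had a value among probes well above background on all 12 arrays. The named changes were picked for their size on these same arrays, so this share is not that of all calls. Of 46 list calls, 38 were kept whichever array was left out. Over all lists and alternatives other than leaving out an array, 1134 results were the same, 85 gained a call, 78 lost one and 3 reversed, and leaving out an array gave 896, 21, 19 and 0. For the counts of changed probes 53 of 72 alternatives stayed within 1.5 times. Except where a setting is said to change only what is tested, the cause was not tested. The comparisons are in the order of the report.

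A 2-fold minimum, stricter by construction, left 995, 1101, 1381, 1906 and 676 probes. Median centring left 5655, 5358, 5719, 6628 and 1432, called 9 lists for rss3 without salt, and gave RSS3 -0.22 there and 0.33 for salt in rss3, both no longer past the threshold. It moved the median of all probes to 0.115 for salt in wild type and reversed ribosomal proteins in the interaction (-0.15). With Agilent's processed signals RSS3 lost its call for salt in rss3 (0.26), and 11 lists were called for rss3 with salt. Rises made up 84.9%, 80.1%, 78.6%, 73.1% and 48.7% of changed probes with median centring, and 45.1%, 41.6%, 42.1%, 39.1% and 47.5% with Cy5 alone, which called 9 lists for salt in rss3, 11 for rss3 with salt and 5 for the interaction. No filter left 5 lists for the interaction. Lists without members matched by accident, chosen after seeing the data, reversed seed storage for salt in wild type (-0.14). Camera with an estimated correlation called 0 lists in each comparison, and fry 19, 23, 18, 20 and 5, with heat shock for salt in rss3 in the other direction (0.024).

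In the authors' table the RankProduct p after Benjamini-Hochberg passed for 2021, 2191 and 2061 probes (salt in wild type, rss3 without and with salt) and the pfp for 1661, 1709 and 1686, of which 1629, 1677 and 1680 were called here in the same direction. Unadjusted, 7716 passed for rss3 with salt. Its interaction by 2-way ANOVA passed for 0 probes after Benjamini-Hochberg (2992 unadjusted), and the same ANOVA on the values used here for 3883 (9026 unadjusted), against 4478 by limma. Leaving out each array gave 2828 to 4923 probes for the interaction, lowest without wild type 0 mM replicate 1 (2828) or 2 (2852) or rss3 0 mM replicate 2 (2925). RSS3 ranged from -0.40 to -0.29 without salt, 0.25 to 0.36 for salt in rss3 and 0.30 to 0.46 for the interaction, and the lists called from 4 to 10 for salt in rss3 and 4 to 8 for the interaction. Signal over background limits which probes were tested and leaves the size of a change uncertain where a group is at background. Quantile scaling of average brightness left the log ratios as they were and tests nothing. RankProduct was not run again, and the interaction needs all 12 arrays, so it has no value from fewer groups.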

Other observations

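Among hormone and transcription factor genes, auxin response and transport loci went up more often than down, with 25 to 42 of 90 higher and 7 to 17 lower over the 4 comparisons between groups, and no list call (smallest adjusted p = 0.080). Cytokinin and ethylene genes had 22 to 26 of 68 higher and 8 to 19 lower (smallest adjusted p = 0.094), and AP2/ERF factors 21 to 27 of 73 higher and 13 to 18 lower (smallest adjusted p = 0.42). Terpenoid phytoalexin genes were mostly unmeasured, and of 10 at most 4 were higher and at most 3 lower (smallest adjusted p = 0.23). Heat shock proteins and chaperones had 14 to 38 of 170 higher and 22 to 34 lower (smallest adjusted p = 0.072).

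Of the lists for other tissues and cell types, Casparian strip, suberin and root hair genes had 8 to 11 of 25 higher and 0 to 5 lower (smallest adjusted p = 0.061), and the secondary wall and vascular list held 1 measured locus, too few for a test. Photosynthesis genes had 10 to 32 of 80 higher and 10 to 17 lower (smallest adjusted p = 0.12). Without members matched by accident, 3 to 21 of 56 were higher and 4 to 11 lower (smallest camera adjusted p = 0.072). Seed storage genes were called for salt in wild type (17 higher, 5 lower of 38, median 0.23, adjusted p = 0.023, or 0.27 with an estimated correlation). That list holds lipid transfer proteins matched by name, and without these and other such members its 16 loci had 3 higher and 5 lower. The call was also lost with no filter on dim probes (0.005) and with median centring (0.29).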
